A study of Homo sapiens with 8 samples.

How the data were processed

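The samples were 8 RNA sequencing libraries of the human pancreatic adenocarcinoma line PATU-8902, which the growth protocol also spells PA-TU-8902 and the cell line label spells A-TU-8902. The groups were taken from the titles and labels: shNTC (2 libraries) and shYAP_TAZ (3 libraries), both labelled sensitive to GNE-7883, and resistant (3 libraries), labelled resistant to it. Per the labels' protocols, the resistant line was grown in culture from a shYAP/WWTR1 tumour of a nude mouse and studied under doxycycline, and the parental shNTC and shYAP/WWTR1 cells were the controls. The description of every library says xenograft, whereas the extraction protocol says that cell lines were lysed on the plate. RNA was purified and made into libraries with the TrueSeq RNA Sample Preparation kit v2 and sequenced as single-end reads of 50 bases on a HiSeq2500, per the labels' protocols. Reads were aligned with GSNAP to GRCh38.p10 and limma was used, per the submitters' processing notes. The counting tool, the annotation, whether counting used the strand, and the limma model are not given there.

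The deposited count table holds raw counts, as whole numbers per Ensembl gene and library. The deposited RPKM table holds RPKM values, counts scaled for gene length and library depth, as computed by the authors. Checked on 186545 values, each RPKM value equalled the count divided by the column total and by 1 constant per gene, with a relative deviation of at most 8.5e-07. Both tables were used, with 0 columns left out. Gene symbols and coordinates came from GENCODE release 29 on GRCh38. Of 58302 genes 57532 had a symbol, and of the 16256 tested genes 16169 had a symbol and 16222 a position.

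Total counts were 17521154 to 22629727 per library, and the tested genes held 99.9% of them. Intervals and floors cover counting error only. The chi-square per degree of freedom over genes with at least 20 counts per pair ran from 2.11 to 7.61 within groups and from 86.2 to 130 between groups. A group without a count was set to a floor of 3 counts over its libraries, which makes its fold a lower bound. Ratios over 1 to 3 counts carry a 95% interval of the count.

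The main test used edgeR 4.0.16 in R 4.3.3 on the counts, with TMM factors, the filterByExpr low-count filter, 1 quasi-likelihood fit of all 8 libraries with a term for group, and 3 contrasts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and 2-fold counts also needed a fold change of at least 2. The common biological coefficient of variation was 5.35% and the median prior degrees of freedom were 15.1. CPM values are counts scaled to library totals (cpm of edgeR) with TMM factors, log2 CPM used a prior count of 2, and tests were two-sided. The groups were compared as shYAP_TAZ with shNTC, resistant with shYAP_TAZ and resistant with shNTC, and knockdown-called genes were counted by their direction in the second of these. The relation expected from the shared shYAP_TAZ libraries was simulated 10 times without group effects.

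The 27 gene lists, with 541 entries, were tested with camera of limma 3.58.1 on voom values with the preset correlation of 0.01, and again with a correlation estimated per list and with fry, which tests whether members move on balance in 1 direction. Adjustment was over the 27 lists. They were YAP/TAZ-TEAD targets, Hippo components, MAPK output, AP-1 factors, receptor tyrosine kinases, their ligands, RAS-MAPK components, mesenchymal, epithelial, classical and basal-like tumour genes, cell cycle, apoptosis, interferon-stimulated, cytokine and NF-kB, TGF-beta, Wnt and Notch targets, cholesterol synthesis, hypoxia and glycolysis, ATF4 response, mitochondrially encoded, integrin and focal adhesion, matrix and protease genes, and markers of fibroblasts, endothelium and leukocytes.

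Genes were named by a fixed rule. It took YAP1, WWTR1 and TEAD1 to TEAD4. For each comparison it took the 6 largest rises and 6 largest falls with adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between libraries, without unnamed or non-coding loci. For each list it took members by size of change with adjusted p under 0.05 and at least 1 CPM in the higher group, up to 4 for lists 1 to 9 and 2 for the others, plus up to 2 against the majority. It also took the most abundant marker of each other cell type. The groups, tests, lists, naming rule and alternatives named below, unless said otherwise, were set before the data were examined. A few genes that the rule took are not reported here. Genes outside the rule are given as chosen after their values were seen, as are COL1A2, COL3A1 and PTPRC in the report.

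The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no low-count filter beyond 1 count over the libraries, at least 1 CPM in 3 libraries, only the 2 groups compared, the replicate number as a block, limma-trend on log2(RPKM + 0.1) and log2(RPKM + 1), each library left out, and a 2-fold threshold for genes moving back. Leaving out the genes of chromosomes 8 and 9 was chosen after seeing the data. Shifts by chromosome used 11352 genes with a mean log2 CPM of at least 2, windows of 10 Mb with at least 15 genes, 10000 random gene sets, and GC content and transcript length known for 16221 genes (99.8%). On data simulated from these libraries with 16256 genes and 50 changed genes per size, the test recovered 86%, 90% and 88% of 2-fold changes in the 3 comparisons, in the order above, and 52%, 58% and 48% of 1.25-fold changes. It called 0.227%, 0.201% and 0.24% of the unchanged genes. A lowering of chromosome 9 simulated at -0.42 on the log2 scale was recovered as -0.40 in resistant against shYAP_TAZ.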

Results

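RNA sequencing was carried out on 8 libraries from derivatives of PATU-8902, a human pancreatic adenocarcinoma cell line. The series asks how tumour cells come to resist inhibition of TEAD, the transcription factor family through which the Hippo pathway coactivators YAP (gene YAP1) and TAZ (gene WWTR1) act. A line with a control hairpin (shNTC, 2 libraries) and a line with hairpins against YAP1 and WWTR1 (shYAP_TAZ, 3 libraries) are both labelled as sensitive to the TEAD inhibitor GNE-7883. The third group (resistant, 3 libraries) is a line propagated in culture from a shYAP/WWTR1 xenograft tumour of a nude mouse, studied under doxycycline and labelled as resistant to the same compound. Whether the shNTC and shYAP_TAZ libraries were made with doxycycline is not given in the sources used here. Total counts ran from 17521154 to 22629727 per library. The log2 CPM values of libraries of the same group correlated across genes with r of at least 0.994. Of 58302 genes, 16256 had enough counts to be tested. The labels do not say that libraries of a group came from separate cultures, and the 3 resistant libraries come from 1 tumour-derived line, so the p-values measure only the spread between these libraries.

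Both hairpin targets were lower in every shYAP_TAZ library than in every shNTC library. YAP1 (ENSG00000137693, chromosome 11, 102110461 to 102233423 in GRCh38 by GENCODE 29) went from 382 ± 9.26 CPM (SD, n = 2) in shNTC to 156 ± 0.85 CPM (SD, n = 3) in shYAP_TAZ, a log2 fold change of -1.29 ± 0.06 (SE, edgeR adjusted p = 6.2e-14). WWTR1 (ENSG00000018408, chromosome 3, 149517235 to 149736714) went from 126 ± 0.774 CPM to 50.2 ± 0.882 CPM (-1.33 ± 0.07, adjusted p = 4.5e-13). In the resistant line YAP1 was lower again, at 102 ± 2.82 CPM (SD, n = 3) (-0.62 ± 0.05 against shYAP_TAZ, adjusted p = 2.1e-09). WWTR1 was partly higher again, at 71.1 ± 4.69 CPM (0.50 ± 0.06 against shYAP_TAZ, adjusted p = 4.3e-07), and still below shNTC (-0.82 ± 0.06, adjusted p = 6.1e-10). Of the 4 TEAD genes, TEAD2 (ENSG00000074219, chromosome 19, 49340595 to 49362457) fell in the resistant line from 24.9 ± 1.52 CPM to 2.54 ± 0.249 CPM (-3.29 ± 0.11, adjusted p = 1.2e-15). TEAD4, the most abundant of them, was at 192 ± 27.0 CPM, 181 ± 10.5 CPM and 175 ± 6.33 CPM in shNTC, shYAP_TAZ and resistant libraries. Neither it nor TEAD3 passed the test in any comparison. TEAD1 was 0.21 ± 0.07 after knockdown (adjusted p = 0.017) and -0.17 ± 0.07 in resistant against shYAP_TAZ (adjusted p = 0.0317). These small TEAD differences turned on single libraries. Without shNTC replicate 2 the TEAD1 call after knockdown was lost (adjusted p = 0.22) and TEAD4 passed the test (-0.23, adjusted p = 0.0137). Without shNTC replicate 1 TEAD2 passed it (0.28, adjusted p = 0.0233). The same TEAD1 call was lost without shYAP_TAZ replicate 2 (adjusted p = 0.0527). The one in resistant against shYAP_TAZ was lost without shYAP_TAZ replicate 1 (0.0945), shYAP_TAZ replicate 2 (0.0928) or resistant replicate 1 (0.164). In resistant against shNTC, TEAD4 and TEAD3 passed it without shNTC replicate 2 (adjusted p = 0.00306 and 0.0483), and TEAD3 did so without resistant replicate 3 (0.0302).

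**Figure D1:**
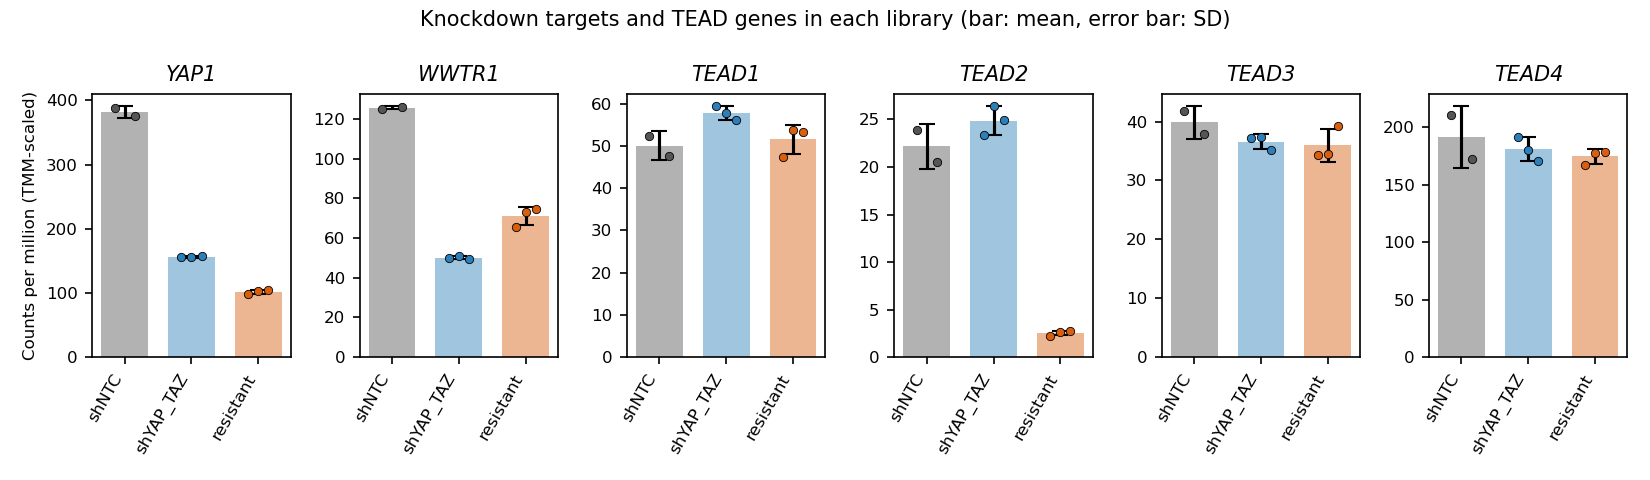
CPM, the usual depth-scaled counts (vertical axes, linear from 0) of YAP1, WWTR1 and the 4 TEAD genes in the shNTC (n = 2), shYAP_TAZ (n = 3) and resistant (n = 3) libraries, with points for libraries, bars for group means and error bars for SD. YAP1 steps down from 382 to 156 to 102 CPM, WWTR1 goes from 126 to 50.2 to 71.1 CPM, and TEAD2 drops to 2.54 CPM in the resistant line.

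The comparison of shYAP_TAZ with shNTC sets the line with lower YAP1 and WWTR1 against the control line. Effects of the hairpins cannot be told apart here from other differences between these lines. Changes after knockdown, or by the knockdown, are differences in this comparison throughout. By camera with the preset correlation, cell cycle and amino acid stress genes were lower as lists, and cholesterol synthesis, extracellular matrix, TGF-beta target and growth factor ligand genes were higher. With an estimated correlation only the amino acid stress list held (adjusted p = 0.0493), and the other 5 were between 0.0588 and 0.532. Of 28 cell cycle genes, 25 fell and 3 rose (median log2 fold change -1.09, camera adjusted p = 8.5e-10 and 0.0588 with an estimated correlation). FOXM1, a transcription factor of mitotic genes, went from 1211 ± 111 to 141 ± 11.8 CPM, and CCNB1, the mitotic cyclin B1, from 443 ± 51.5 to 62.1 ± 2.87 CPM. CCNE1 (cyclin E1) and E2F1 rose instead by 1.05 ± 0.09 and 0.81 ± 0.08 on the log2 scale. Of 19 genes of the ATF4 amino acid response, 18 fell and none rose (median log2 fold change -0.81, camera adjusted p = 4.2e-07 and 0.0493 with an estimated correlation). SLC7A5, the large neutral amino acid transporter, fell from 1347 ± 179.6 to 255 ± 9.73 CPM (-2.40 ± 0.07, adjusted p = 2.0e-16). Among 24 cholesterol synthesis genes 21 rose, with LSS at 1.46 ± 0.08 and HMGCS1 at 1.38 ± 0.06. That list (median log2 fold change 0.53, camera adjusted p = 4.9e-07 and 0.0588 with an estimated correlation) had 1 lower gene over all genes tested and 2 adjusted over the list alone.

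Extracellular matrix and matrix protease genes rose in 15 of 23 cases and fell in 4 (median log2 fold change 1.05, camera adjusted p = 9.6e-04 and 0.488 with an estimated correlation). COL6A1, a collagen VI chain, went from 20.5 ± 5.11 to 189 ± 21.7 CPM (3.21 ± 0.12). The collagenase MMP1 rose by 3.44 ± 0.39, and the matrix glycoprotein TNC (tenascin C) went the other way (-2.90 ± 0.18). TGF-beta target genes rose in 11 of 16 cases and fell in 4 (median log2 fold change 0.70, camera adjusted p = 0.00877 and 0.532 with an estimated correlation), among them the cell cycle inhibitor CDKN2B, from 29.2 ± 1.30 to 121 ± 1.59 CPM. Ligands of receptor tyrosine kinases rose in 9 of 13 cases and fell in 2 (median log2 fold change 0.54, camera adjusted p = 0.0117 and 0.164 with an estimated correlation), with IGF2 at 2.37 ± 0.11 and PDGFA at 1.96 ± 0.09. FGF19 (-2.71 ± 0.33) and TGFA (-0.25 ± 0.06) fell. Marker genes of other cell types moved beside the matrix genes. Among 5 tested endothelial markers 3 rose, including VWF (from 0.802 to 9.40 CPM), and 1 fell (camera adjusted p = 0.0996, and 0.0305 under a stricter low-count filter or 0.0186 with only the 2 groups fitted). Among 6 fibroblast markers 2 rose, including COL1A1 (from 1.85 to 5.80 CPM), and ACTA2 fell (from 15.4 to 5.73 CPM, list adjusted p = 0.548). Of 3 leukocyte markers only LAPTM5 rose, from 1.72 to 2.74 CPM (list adjusted p = 0.455), and its call was lost without shNTC replicate 2 (adjusted p = 0.0835).

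The YAP/TAZ-TEAD target genes did not move as a list. Of 20 tested members 5 rose, 6 fell and 9 did not pass the test (median 0.00, mean -0.11, camera direction down, adjusted p = 0.816). ANKRD1, a widely used YAP target, fell from 16.6 ± 2.23 to 2.77 ± 0.192 CPM (-2.58 ± 0.13, adjusted p = 3.7e-13). IGFBP3 fell from 137 ± 11.9 to 66.8 ± 1.80 CPM. F3, the coagulation tissue factor, rose from 253 ± 13.3 to 496 ± 15.7 CPM and FJX1 from 4.18 ± 0.859 to 8.19 ± 0.249 CPM. Hippo pathway components were also split, with 7 higher and 8 lower of 24 (adjusted p = 0.816). The scaffold SAV1 (1.20 ± 0.07) and the kinase LATS2 (0.87 ± 0.09) rose beside the fall of YAP1 and WWTR1. Genes read out from MAPK signalling included 8 that rose and 5 that fell of 16, and the list did not pass the test (median 0.15, adjusted p = 0.0816, and 0.0335 without shNTC replicate 1). The ERK phosphatase DUSP5 rose from 23.9 ± 1.75 to 171 ± 0.829 CPM (2.83 ± 0.07), SPRY4 from 84.6 ± 11.7 to 234 ± 4.76 CPM and CCND1 (cyclin D1) from 356 ± 58.7 to 861 ± 38.6 CPM. The ETS factors ETV1 (1.53 ± 0.10) and ETV5 (-1.17 ± 0.06) went in opposite directions. AP-1 factors rose in 8 of 11 cases, including JUN (1.12 ± 0.08) and MAFF (1.05 ± 0.07), with ATF3 lower (-1.04 ± 0.12). That list passed the test only without shNTC replicate 1 (adjusted p = 0.0481) or shYAP_TAZ replicate 3 (0.0496), against 0.0775 with all libraries.

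Lists of cell state were mixed after knockdown. Mesenchymal genes counted 8 higher and 3 lower of 15, with 4 lower when adjusted over the list alone (adjusted p = 0.209), and ZEB1, a repressor of epithelial genes, rose from 1.41 ± 0.0231 to 11.3 ± 0.855 CPM. Epithelial genes counted 12 higher and 7 lower of 24 (adjusted p = 0.3), with CLDN3 up (1.60 ± 0.08) and EHF down (-0.99 ± 0.06). The remaining lists did not pass the camera test. Basal-like tumour genes (10 higher and 2 lower of 17, adjusted p = 0.0996) and classical tumour genes (2 higher and 3 lower of 8, adjusted p = 0.788) were not called as lists. Receptor tyrosine kinases (7 higher and 4 lower of 17, adjusted p = 0.3) and RAS-MAPK cascade components (9 higher and 3 lower of 20, adjusted p = 0.184) were not called either. Integrin and focal adhesion genes (12 higher and 6 lower of 20, adjusted p = 0.143) and apoptosis regulators (10 higher and 4 lower of 19, adjusted p = 0.177) were not called as lists. Interferon-stimulated genes (6 higher and 13 lower of 22, adjusted p = 0.229) and cytokine and NF-kB target genes (11 higher and 3 lower of 18, adjusted p = 0.0803) were not called either. The classical list had a median of -0.33 and a mean of -0.54, and fry put it in the other direction. Adjusted over the list alone, 7 interferon-stimulated genes were higher, and the cytokine list passed the test without shNTC replicate 2 (adjusted p = 0.0201). Wnt target genes (1 higher and 5 lower of 10, adjusted p = 0.0996) and Notch target genes (4 higher and 2 lower of 8, adjusted p = 0.232) were not called as lists. Hypoxia and glycolysis genes (8 higher and 9 lower of 23, adjusted p = 0.744) and mitochondrially encoded genes (0 higher and 3 lower of 13, adjusted p = 0.209) were not called either.

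The 6 genes with the largest rise after knockdown included 3 without a single count in shNTC. MLPH, a linker of melanosomes to myosin (chromosome 2, 237485428 to 237555318), reached 14.5 ± 1.24 CPM (SD, n = 3), at least 189-fold higher than the level of 3 counts over the shNTC libraries. CYP2A13, a cytochrome P450 (7.45 ± 0.298 CPM), was at least 97.0-fold higher. TNFRSF17, the plasma cell receptor BCMA (5.92 ± 0.44 CPM), was at least 77.1-fold higher. The integrin subunit ITGB2 rose from 0.403 ± 0.0863 to 24.3 ± 0.544 CPM. The secreted phospholipase PLA2G5 rose from 0.374 ± 0.127 to 18.2 ± 0.658 CPM and the ligand WNT7A from 0.287 ± 0.0777 to 9.15 ± 0.476 CPM. The largest falls were those of SCNN1G, a subunit of the epithelial sodium channel (7.93 ± 0.714 to 0.113 ± 0.0298 CPM), METTL7A (21.9 ± 2.07 to 0.393 ± 0.196 CPM) and the proteoglycan SRGN (6.11 ± 1.39 to 0.19 ± 0.0861 CPM). They were followed by the carbonic anhydrase CA9 (36.5 ± 3.10 to 1.45 ± 0.331 CPM), CASP14 (5.95 ± 0.115 to 0.254 ± 0.105 CPM) and PPP1R1B (7.08 ± 0.421 to 0.371 ± 0.0639 CPM). Their log2 fold changes ran from -6.06 ± 0.27 for SCNN1G to -4.24 ± 0.22 for PPP1R1B (adjusted p at most 1.4e-11 for CASP14). Genes of chromosome 8 had a median log2 fold change of -0.31 over 399 genes in this comparison, with 11 of 12 windows of 10 Mb below the genome median, so the lines also differed by a shift along a chromosome. In all, edgeR called 4929 genes higher and 4941 lower of 16256, of which 1337 and 1321 changed at least 2-fold. Camera called 6 of 27 lists with the preset correlation of 0.01, and the ATF4 list was the 1 call that held with an estimated correlation.

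The resistant line was next set against its sensitive shYAP_TAZ counterpart. In both comparisons of the resistant line, resistance cannot be told apart from passage through the mouse, any difference in doxycycline or other differences between the lines. By camera with the preset correlation, inflammatory cytokine and NF-kB target genes, cell cycle genes and ATF4 response genes were among the lists that were higher. Hypoxia and glycolysis genes, Hippo components, TGF-beta targets and receptor tyrosine kinases were lower. None of the 11 list calls held with an estimated correlation (adjusted p = 0.163 to 0.734), and other divisions of the same 6 libraries gave up to 8 calls. Those divisions mix libraries of both groups and keep part of their difference, so they do not show calls without a difference. Of 18 cytokine and NF-kB target genes 16 rose and none fell (median log2 fold change 1.35, camera adjusted p = 3.8e-08 and 0.393 with an estimated correlation). The chemokine CXCL8 went from 14.3 ± 1.72 to 143 ± 17.3 CPM (3.32 ± 0.13, adjusted p = 7.9e-15). The cytokine IL1B went from 59.0 ± 2.24 to 580.3 ± 4.02 CPM (3.30 ± 0.07, adjusted p = 8.8e-19). Of 28 cell cycle genes 18 rose and 6 fell, 7 when adjusted over the list alone (median log2 fold change 0.96, camera adjusted p = 6.5e-05 and 0.344 with an estimated correlation). CCNB2 went from 28.6 ± 1.63 to 174 ± 8.29 CPM and CCNB1 from 62.1 ± 2.87 to 325 ± 23.7 CPM. CCNE2 (from 15.9 to 7.95 CPM) and the replication helicase subunit MCM4 (-0.80 ± 0.05) fell. ATF4 response genes rose in 17 of 19 cases and fell in 1 (median log2 fold change 0.43, camera adjusted p = 1.8e-04 and 0.163 with an estimated correlation). NUPR1 went from 0.61 ± 0.15 to 6.73 ± 0.647 CPM, and VLDLR fell (-1.69 ± 0.12).

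Hypoxia and glycolysis genes fell in 17 of 23 cases and rose in 3 (median log2 fold change -0.48, camera adjusted p = 1.2e-04 and 0.658 with an estimated correlation). The prolyl hydroxylase EGLN3 went from 10.2 ± 0.506 to 1.86 ± 0.0347 CPM and NDRG1 from 31.8 ± 2.88 to 6.31 ± 1.33 CPM. Hippo components fell in 15 of 24 cases and rose in 2 (median log2 fold change -0.28, camera adjusted p = 0.012 and 0.721 with an estimated correlation). Beside TEAD2 these were the TEAD cofactor VGLL1 (-0.96 ± 0.08), the phosphatase PTPN14 (-0.86 ± 0.09) and the kinase LATS1 (-0.72 ± 0.06), while the upstream tumour suppressor NF2 rose (0.35 ± 0.08). TGF-beta targets fell in 11 of 16 cases and rose in 4 (median log2 fold change -0.70, camera adjusted p = 0.019 and 0.721 with an estimated correlation). The inhibitory SMADs led the fall, SMAD6 from 21.7 ± 2.03 to 3.28 ± 0.457 CPM and SMAD7 from 16.2 ± 1.26 to 2.55 ± 0.468 CPM. LTBP2 (1.23 ± 0.07) was among those that rose. Receptor tyrosine kinases fell in 11 of 17 cases and rose in 4 (median log2 fold change -0.33, camera adjusted p = 0.0264 and 0.734 with an estimated correlation). FGFR3 went from 14.8 ± 0.786 to 4.35 ± 0.0583 CPM, MERTK changed by -0.94 ± 0.09 and EPHB4 by -0.81 ± 0.08. Mitochondrially encoded genes rose in 9 of 13 cases and fell in 0 (median log2 fold change 0.41, camera adjusted p = 0.012 and 0.734 with an estimated correlation). The estimated correlation of these genes was 0.971, so the preset of 0.01 treated them as far more independent than they were. Their share of all counts was 1.38%, 1.27% and 0.953% in resistant replicates 1, 2 and 3, against 0.844% to 0.939% in shYAP_TAZ, so the third resistant library lay close to the knockdown libraries.

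Epithelial genes rose in 14 of 24 cases and fell in 5 (median log2 fold change 0.22, camera adjusted p = 0.0264 and 0.721 with an estimated correlation). The tight junction genes CLDN1 and CLDN4 went from 84.9 ± 1.96 to 233 ± 21.0 CPM and from 316 ± 18.9 to 807 ± 32.4 CPM. The desmosomal gene DSP fell (-1.12 ± 0.07). Extracellular matrix and protease genes rose in 15 of 23 cases and fell in 6 (median log2 fold change 0.47, camera adjusted p = 0.0264 and 0.721 with an estimated correlation). TNC went from 1.68 ± 0.304 to 40.0 ± 6.16 CPM and the collagenase MMP13 from 0.919 ± 0.185 to 15.8 ± 1.86 CPM, whereas COL17A1, a hemidesmosome collagen, fell (-1.99 ± 0.08). The call of this list was lost (adjusted p = 0.0915) when the genes of chromosomes 8 and 9 were left out, a setting chosen after the data had been seen. Markers of other cell types moved beside these genes. The 3 tested leukocyte markers all rose (median log2 fold change 1.72, camera adjusted p = 0.0264 and 0.658 with an estimated correlation), with LAPTM5 at 1.72 ± 0.13, CORO1A at 0.89 ± 0.09 and ITGAM at 2.51 ± 0.36. Fibroblast markers rose in 4 of 6 cases and fell in 2 (list adjusted p = 0.464), COL1A1 reaching 11.7 ± 0.471 CPM. Endothelial markers fell in 3 of 5 (list adjusted p = 0.13), EGFL7 from 105 ± 7.13 to 36.4 ± 0.814 CPM. The latter list passed the test under the stricter low-count filter (adjusted p = 0.0164) and when only the 2 groups were fitted (0.0291). The pan-leukocyte gene PTPRC was at 0.0721 CPM in the resistant libraries, and the fibroblast collagens COL1A2 and COL3A1 were at 0.0522 and 0.0167 CPM.

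MAPK output genes did not pass the test as a list, with 4 higher and 8 lower of 16 (median -0.24, adjusted p = 0.149). The lower ones included ETV1 (-3.16 ± 0.10), the ERK phosphatase DUSP4, from 984 ± 22.3 to 364 ± 14.3 CPM, and CCND1, from 861 ± 38.6 to 339 ± 16.6 CPM. EGR1, an immediate early gene of ERK signalling, rose from 12.3 ± 0.616 to 47.4 ± 2.77 CPM and DUSP5 rose further, from 171 ± 0.829 to 283 ± 8.80 CPM. In the RAS-MAPK cascade 2 genes were higher and 10 lower of 20 (adjusted p = 0.211). The kinase MAP3K8, which can act upstream of MEK, rose from 15.7 ± 0.792 to 35.7 ± 1.45 CPM, and NF1, a RAS GTPase-activating protein, fell from 175 ± 21.2 to 115 ± 10.3 CPM. The AP-1 list had 6 higher and 2 lower of 11 (adjusted p = 0.5), with ATF3 (1.46 ± 0.10) and FOSB (1.16 ± 0.18) up and FOSL2 (-1.97 ± 0.07) and JUN (-1.13 ± 0.07) down. YAP/TAZ-TEAD targets again moved both ways, 7 higher and 9 lower of 20 (median 0.03, mean -0.04, camera direction down, adjusted p = 0.747). IGFBP3 rose from 66.8 ± 1.80 to 242 ± 7.94 CPM and ANKRD1 from 2.77 ± 0.192 to 8.35 ± 0.431 CPM. TGFB2 fell (-1.13 ± 0.07).

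Basal-like tumour genes counted 8 higher and 6 lower of 17 (adjusted p = 0.356). The keratins KRT17 and KRT6B, whose reads can be shared with near-identical copies, went from 0.214 ± 0.128 to 19.9 ± 1.57 CPM and from 0.116 ± 0.0824 to 8.51 ± 1.39 CPM. Mesenchymal genes counted 6 higher and 8 lower of 15 (adjusted p = 0.5), ZEB1 falling back from 11.3 ± 0.855 to 2.20 ± 0.27 CPM. The other lists did not pass the test. Growth factor ligands (4 higher and 6 lower of 13, adjusted p = 0.691) and classical tumour genes (4 higher and 3 lower of 8, adjusted p = 0.818) were not called as lists. Apoptosis regulators (7 higher and 7 lower of 19, adjusted p = 0.905) and interferon-stimulated genes (10 higher and 6 lower of 22, adjusted p = 0.727) were not called either. Among the ligands the EGFR ligand AREG rose from 49.1 ± 0.827 to 109 ± 4.93 CPM and GAS6 fell from 764 ± 46.9 to 322 ± 19.2 CPM. Cholesterol synthesis genes (5 higher and 10 lower of 24, adjusted p = 0.277) and Wnt target genes (3 higher and 6 lower of 10, adjusted p = 0.531) were not called as lists. Notch target genes (3 higher and 2 lower of 8, adjusted p = 0.747) and integrin and focal adhesion genes (8 higher and 10 lower of 20, adjusted p = 0.608) were not called either. Of the cholesterol genes 11 were lower when adjusted over the list alone. Camera placed the AP-1, classical and Notch lists up and fry placed them down, with medians of 0.29, 0.68 and 0.26 and means of 0.08, 0.53 and -0.04. The apoptosis list had a median of -0.02 and a mean of 0.04.

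**Figure D2:**
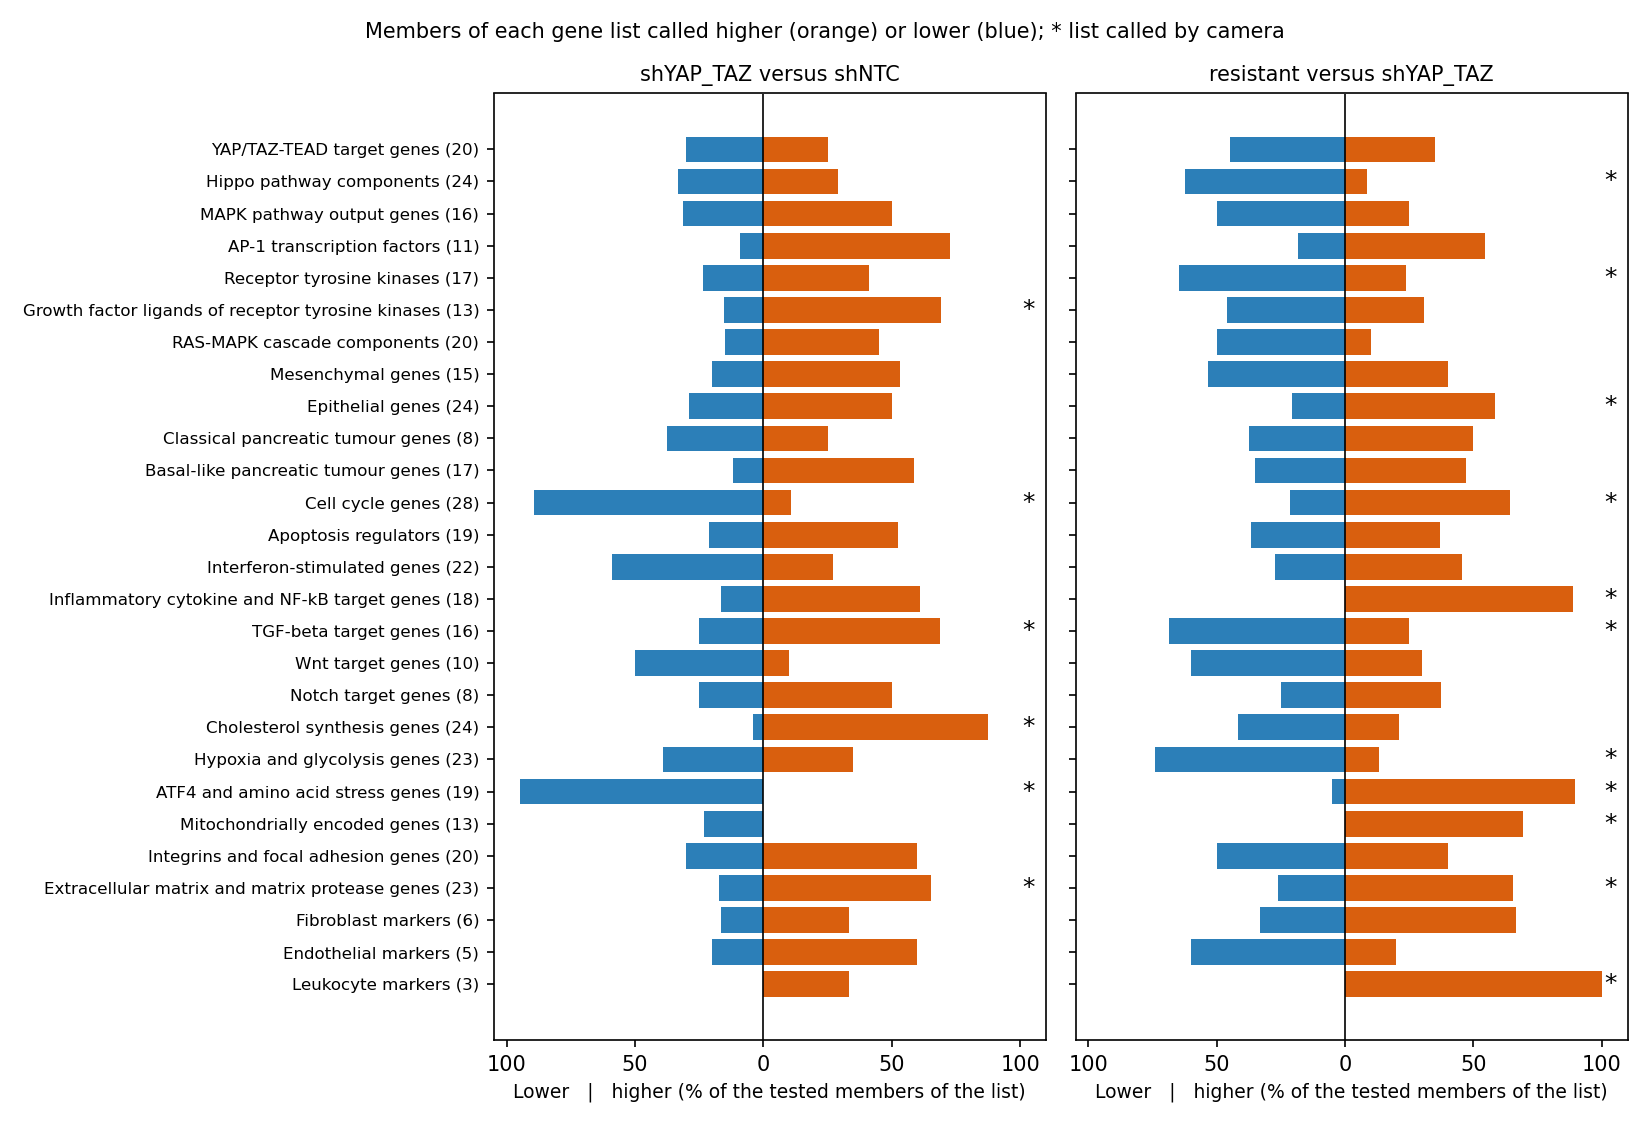
Share of the tested members of each of the 27 gene lists (number tested in parentheses) that edgeR called higher (orange, to the right) or lower (blue, to the left) in shYAP_TAZ against shNTC and in resistant against shYAP_TAZ, in percent of tested members, with an asterisk where camera called the list with the preset correlation of 0.01. Cell cycle and ATF4 genes point to lower after knockdown (25 of 28 and 18 of 19 genes) and to higher in the resistant line (18 of 28 and 17 of 19), and cytokine and NF-kB targets point to higher in the resistant line (16 of 18).

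Among the genes with the largest rise in the resistant line was PAEP, encoding the secreted lipocalin glycodelin (chromosome 9, 135561756 to 135566955), which went from 0.181 ± 0.0852 to 428 ± 8.80 CPM (11.19 ± 0.12, adjusted p = 1.9e-22). SSX1, a cancer-testis antigen gene with near-identical copies (chromosome X, 48255317 to 48267444), had no count in the shYAP_TAZ libraries and 20.2 ± 1.13 CPM (SD, n = 3) in the resistant ones, at least 419.8-fold higher. The cAMP phosphodiesterase PDE4B likewise had no count and reached 7.68 ± 0.548 CPM, at least 159.7-fold higher. SRGN, among the largest falls after knockdown, rose from 0.19 ± 0.0861 to 124 ± 9.61 CPM. The actin crosslinker FLNC rose from 0.109 ± 0.112 to 26.6 ± 1.56 CPM and ASB9 from 0.085 ± 0.108 to 10.3 ± 1.11 CPM. Among the falls, LGR6, a receptor for R-spondins (chromosome 1, 202193901 to 202319781), went from 44.8 ± 2.02 CPM to 3 counts over the resistant libraries, a ratio of 859 (95% counting interval 294 to 4169). The others were FRMD3 (36.3 ± 1.52 to 0.17 ± 0.101 CPM), FAM83B (5.43 ± 0.389 to 0.0896 ± 0.0678 CPM) and the matricellular protein gene CCN3 (27.7 ± 2.39 to 0.828 ± 0.492 CPM). Last came the microvillus gene VIL1 (5.22 ± 0.638 to 0.156 ± 0.0991 CPM) and GDA, guanine deaminase (819 ± 26.2 to 25.4 ± 2.91 CPM). PAEP, FRMD3 and GDA lie on chromosome 9, where the median log2 fold change of 462 genes was -0.55 against -0.01 for the genome. CCN3 lies on chromosome 8 (median -0.18 over 399 genes). So do CCNE2, MCM4, NDRG1 and DUSP4, named above as list members, and VLDLR lies on chromosome 9. The fold changes of genes on these chromosomes may hold the shift along them beside any other difference. In all, 5042 genes were called higher and 5100 lower, of which 1268 and 1107 changed at least 2-fold. Camera called 11 of 27 lists with the preset correlation and 0 with an estimated one, and the direction test fry called 20.

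A further question was whether genes changed by the knockdown moved back in the resistant line. Of 9870 genes called after knockdown, 4985 were called in the opposite direction between shYAP_TAZ and resistant libraries and 1961 in the same direction. Independent lists of these sizes would give 3079 in each case. With a 2-fold change required in both comparisons, 795 genes moved back and 200 moved further, against 194 expected for either. Of the 2658 genes changed at least 2-fold by knockdown, 1502 were called opposite. Of those 1502, 525 no longer differed from shNTC by the test, 845 were still called on the knockdown side of shNTC, and 132 were called beyond it. Another 421 of the 2658 moved further in the knockdown direction, and 735 were not called between shYAP_TAZ and resistant libraries. CCNB1, BIRC5 and ZEB1 were among the genes that moved back, whereas DUSP5, COL6A1 and YAP1 itself moved further. Both comparisons use the same shYAP_TAZ libraries, which by itself gives a negative relation. The lists are therefore not independent, and an excess over 3079 or 194 does not by itself show a return. Across genes, which are not independent replicates, the fold changes correlated with r = -0.27 (Spearman rho = -0.33). The mean r was -0.43 in 10 simulations with no effect. EdgeR called almost no gene in these simulations, so their mean of 0 genes called in opposite directions was fixed in advance. It is no measure for the 4985. The observed covariance was -0.223 and the simulated one -0.017, a difference of -0.206. The simulations hold only the spread between libraries, which therefore does not account for that difference. A deviation common to the 3 shared libraries was not simulated and may be part of it. These libraries cannot be split into sets of at least 2 each to check this.

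The last comparison set the resistant line against the shNTC control, which places the resistant cells relative to cells without the knockdown. By camera with the preset correlation, cytokine and NF-kB target, matrix, cholesterol synthesis, epithelial and basal-like tumour gene lists were among those higher in the resistant line, and hypoxia and glycolysis genes were lower. None of the 10 list calls held with an estimated correlation (adjusted p = 0.373 to 0.682). Of 18 cytokine and NF-kB target genes 17 rose and none fell (median log2 fold change 1.84, camera adjusted p = 6.0e-09 and 0.373 with an estimated correlation). IL1B stood at 580.3 ± 4.02 CPM against 42.0 ± 7.08 CPM. Matrix and protease genes rose in 17 of 23 cases and fell in 3 (median log2 fold change 1.46, camera adjusted p = 8.7e-05 and 0.373 with an estimated correlation). COL6A1 went from 20.5 ± 5.11 to 1801 ± 126 CPM and MMP1 from 0.235 ± 0.0702 to 20.3 ± 3.17 CPM. Beside them the 3 leukocyte markers rose (median log2 fold change 2.39, camera adjusted p = 0.0349 and 0.373 with an estimated correlation), and the call was lost without shNTC replicate 1 (adjusted p = 0.122). Fibroblast markers rose in 4 of 6 cases and fell in 2 (list adjusted p = 0.362), and endothelial markers counted 1 higher and 2 lower of 5 (list adjusted p = 0.834). Hypoxia and glycolysis genes fell in 17 of 23 cases, 18 when adjusted over the list alone, and rose in 3 (median log2 fold change -0.50, camera adjusted p = 1.8e-04 and 0.373 with an estimated correlation). CA9 went from 36.5 ± 3.10 to 0.505 ± 0.00839 CPM and the vasodilator peptide gene ADM from 68.3 ± 10.4 to 15.3 ± 0.912 CPM. The hexokinase HK2 rose (0.59 ± 0.07).

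Cholesterol synthesis genes stood above shNTC in 16 of 24 cases and below it in 2 (median log2 fold change 0.39, camera adjusted p = 1.8e-04 and 0.373 with an estimated correlation), LSS and MVD at 1.43 ± 0.08 and 1.38 ± 0.09. Epithelial genes rose in 15 of 24 cases and fell in 5 (median log2 fold change 0.62, camera adjusted p = 0.00337 and 0.373 with an estimated correlation), and CLDN7 went from 219 ± 7.96 to 566 ± 31.9 CPM. Basal-like tumour genes rose in 12 of 17 cases and fell in 5 (median log2 fold change 0.69, camera adjusted p = 0.0249 and 0.373 with an estimated correlation). KRT6A went from 0.173 ± 0.0835 to 51.7 ± 3.71 CPM. KRT6B was 167 times higher over 2 shNTC counts (95% counting interval 46.0 to 1383), and near-identical keratins can share the reads of both. KRT6B and KRT17 (10 counts over the shNTC libraries) passed the low-count filter only through the resistant group. The basal-like call therefore rests in part on that selection. The squamous factor TP63 fell (-2.02 ± 0.37). Cell cycle genes stood below shNTC in 15 of 28 cases and above it in 4 (median log2 fold change -0.28, camera adjusted p = 0.0259 and 0.373 with an estimated correlation). CCNE1 was higher (from 14.3 to 62.6 CPM) and CCNE2 lower (from 24.3 to 7.95 CPM). Hippo components were lower in 12 of 24 cases and higher in 4 (median log2 fold change -0.19, camera adjusted p = 0.0462 and 0.682 with an estimated correlation). That call was lost without shNTC replicate 1 (adjusted p = 0.122) or resistant replicate 1 (0.0776), with upper quartile scaling (0.0505) and under the stricter low-count filter (0.0541). AP-1 factors were higher in 6 of 11 cases and lower in 1 (median log2 fold change 0.58, camera adjusted p = 0.0486 and 0.423 with an estimated correlation). Their call was lost without shNTC replicate 2 (0.072), resistant replicate 1 (0.0503) or resistant replicate 3 (0.0584), and in 7 settings in all (0.0503 to 0.072). With the genes of chromosomes 8 and 9 left out, a setting chosen after the data had been seen, the Hippo, AP-1, basal-like, cell cycle and leukocyte calls were lost (adjusted p from 0.0503 to 0.0683).

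YAP/TAZ-TEAD targets (7 higher and 9 lower of 20, adjusted p = 0.868) and MAPK output genes (4 higher and 7 lower of 16, adjusted p = 0.868) were not called as lists. RAS-MAPK cascade components (7 higher and 6 lower of 20, adjusted p = 0.715) and receptor tyrosine kinases (4 higher and 7 lower of 17, adjusted p = 0.543) were not called either. Of the YAP/TAZ-TEAD targets 8 were higher when adjusted over the list alone. The list's median of 0.13 and mean of -0.15 differed in sign, with the camera direction down. So did those of the MAPK output list (-0.02 and 0.12, camera down and fry up) and the RAS-MAPK list (-0.06 and 0.12, camera up). TGFB2 (-1.83 ± 0.08) and CRIM1 (-1.31 ± 0.07) were lower and F3 was higher (1.15 ± 0.06). Among MAPK output genes DUSP5 went from 23.9 ± 1.75 to 283 ± 8.80 CPM and DUSP6 changed by -0.88 ± 0.07. Growth factor ligands (8 higher and 5 lower of 13, adjusted p = 0.203) and mesenchymal genes (9 higher and 4 lower of 15, adjusted p = 0.247) were not called as lists. Classical tumour genes (4 higher and 3 lower of 8, adjusted p = 0.834) and apoptosis regulators (10 higher and 4 lower of 19, adjusted p = 0.0844) were not called either. PDGFB rose from 17.1 ± 0.885 to 89.4 ± 0.969 CPM and the cadherin CDH2 fell from 6.67 ± 0.242 to 1.19 ± 0.319 CPM. Interferon-stimulated genes (4 higher and 10 lower of 22, adjusted p = 0.362) and TGF-beta targets (8 higher and 4 lower of 16, adjusted p = 0.362) were not called as lists. Wnt targets (3 higher and 6 lower of 10, adjusted p = 0.228) and Notch targets (5 higher and 1 lower of 8, adjusted p = 0.203) were not called either. ATF4 response genes (5 higher and 9 lower of 19, adjusted p = 0.184) and integrin and focal adhesion genes (9 higher and 9 lower of 20, adjusted p = 0.511) were not called as lists. Mitochondrially encoded genes (8 higher and 2 lower of 13, adjusted p = 0.203) were not called either. Adjusted over the list alone 9 TGF-beta targets were higher, and the mitochondrial list passed the test without resistant replicate 3 (adjusted p = 0.00415). The Wnt feedback gene AXIN2 went from 6.36 ± 0.271 to 0.12 ± 0.0769 CPM, and TGFBI from 910.2 ± 4.70 to 163 ± 0.865 CPM. Median and test also differed in sign for the classical list (median -0.05, mean -0.01, camera up) and the endothelial list (median 0.29, mean 0.41, camera down), and fry placed the TGF-beta list (median 0.22, mean 0.02, camera up) down.

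Of the largest rises over shNTC, PAEP (at least 5575-fold), SSX1 (at least 263-fold), MLPH (at least 119-fold) and TNFRSF17 (at least 88.2-fold) had no count in shNTC. KRT6A followed (8.12 ± 0.20), and PDE4B was 301 times higher over 1 shNTC count (95% counting interval 53.7 to 11901). The largest falls were those of LZTS1 (chromosome 8, 20246165 to 20303963), from 14.0 ± 2.39 CPM to 1 count over the resistant libraries (ratio 797, 95% counting interval 142 to 31532), and of LGR6 (ratio 533, interval 182 to 2587). FAM83B went from 12.6 ± 1.83 to 0.0896 ± 0.0678 CPM and the nuclear receptor corepressor gene NRIP1 from 95.5 ± 5.98 to 0.78 ± 0.214 CPM. The axon guidance ligand gene SLIT2 went from 53.1 ± 3.89 to 0.571 ± 0.0713 CPM, and CA9 was the last of these. LZTS1 lies on chromosome 8, as does CCNE2 named above, and CA9 lies on chromosome 9. The 399 and 462 tested genes of these chromosomes had median log2 fold changes of -0.54 and -0.51 in this comparison. In all, 4892 genes were called higher and 5306 lower, of which 1624 and 1367 changed at least 2-fold. Camera called 10 of 27 lists with the preset correlation and 0 with an estimated one, and fry called 19.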

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

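The exclusion of chromosomes 8 and 9 was chosen only after the shifts by chromosome were seen, and the other settings were planned. No called gene or list reversed under any setting. The list of classical tumour genes, not called by camera, reversed with fry, which called it up after knockdown (adjusted p = 0.0183, camera down) and down in resistant against shYAP_TAZ (0.0157, camera up). YAP1 and WWTR1 kept their direction and their call in all 3 comparisons under every setting, and 314 of 334 results for named genes kept theirs, or stayed uncalled, under each setting that tested the gene. Only 324 of these results could be had under the stricter filter, 333 with only the 2 groups compared and 305 without chromosomes 8 and 9. Changes of scaling moved the median fold change of all genes by at most 0.061 on the log2 scale. Whether higher or lower genes were more numerous turned with some settings in all 3 comparisons, so no excess of either is claimed. Higher genes were more numerous after knockdown with upper-quartile factors (5161 higher, 4730 lower), no filter (5132 and 4907), both RPKM scales (51.0% and 50.5% of calls higher), without shYAP_TAZ replicate 1 (4721 and 4535) and without chromosomes 8 and 9 (4589 and 4444). In resistant against shNTC they were so with upper-quartile factors (5516 and 4780), both RPKM scales (52.1% and 51.8%) and without chromosomes 8 and 9 (4720 and 4575). In resistant against shYAP_TAZ they were so with RLE factors (5134 and 5021), upper-quartile factors (5442 and 4731), the stricter filter (4802 and 4676) and both RPKM scales (53.4% and 53.6%). The same held there without shYAP_TAZ replicate 2 (4719 and 4587), resistant replicate 3 (4935 and 4860), or chromosomes 8 and 9 (4825 and 4430). The counts of called genes stayed within 1.5 times the reported ones under all settings run on them. DESeq2 gave 4270 higher and 4288 lower genes for shYAP_TAZ against shNTC, 4422 and 4430 for resistant against shYAP_TAZ, and 4295 and 4701 for resistant against shNTC. Leaving out each library in turn gave 4169 to 4721 higher and 4433 to 4746 lower genes in the first comparison, 4543 to 4935 and 4587 to 4860 in the second, 4326 to 4717 and 4825 to 5158 in the third, and 4424 to 4937 genes moving back. Where 1 shNTC library was left, it was assumed to vary like the other groups. At a 2-fold change, limma-trend on log2(RPKM + 1) gave 485 higher and 542 lower genes in the first comparison, 472 and 305 in the second, and 698 and 442 in the third. The pseudocount of 1 shrinks fold changes of genes with low RPKM by construction. With 2-fold changes required in both comparisons, 795 genes moved back, fewer by construction. The replicate number as a block gave 4568 and 4613, 4831 and 4877, and 4545 and 5008 genes higher and lower, 4527 moving back, and 6, 11 and 10 lists. Libraries with the same number in different groups had correlated deviations of either sign (r from -0.38 to 0.38 across genes), so the numbers do not pair the samples. Libraries with different numbers had r from -0.43 to 0.43. The deviations of the 2 shNTC libraries mirror each other by construction. A source of variation common to libraries of different groups was not tested.

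List calls depended most on the set test. With an estimated correlation 1, 0 and 0 lists were called in the 3 comparisons, and with fry, which does not compare a list with other genes, 19, 20 and 19, against 6, 11 and 10. In the ATF4 list in resistant against shYAP_TAZ the estimated correlation was -0.0126, below the preset 0.01. Its camera adjusted p still rose from 1.8e-04 to 0.163. The ligand list after knockdown (-0.0394) went from 0.0117 to 0.164. A correlation above the preset therefore does not account for the loss in these lists. In the other lists that lost the call the estimate was above 0.01, and what changed their call was not tested. Without the genes of chromosomes 8 and 9, 5 lists instead of 10 were called in resistant against shNTC, and the cause was not tested. Of the called gene results 15 lost the call in at least 1 setting. TEAD1 did so after knockdown also with the block (adjusted p = 0.0511) and log2(RPKM + 1) (0.052), and in resistant against shYAP_TAZ with upper-quartile factors (0.0799), DESeq2 (0.0819), the block (0.0634) and both RPKM scales (0.146 and 0.149). The others included HEY2 and LAPTM5 after knockdown, PDGFRB, SLC2A3 and ACTA2 in resistant against shYAP_TAZ, and CCDC80, PDGFRB, ANKRD37, STC2, MT-ND5 and COL6A3 in resistant against shNTC. Depth was not varied, so its part in missing genes near the filter or small changes was not tested. The smallest simulated change was recovered in 52%, 58% and 48% of cases in the 3 comparisons.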

Other observations

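The tests chosen only after the result was seen were those of the gene families and cell cycle parts, of the share of lower genes and of the windows on chromosomes 9 and 8, of the mouse cell markers, of the YAP1 and WWTR1 bound, of the abundant YAP/TAZ-TEAD targets and of the cancer-testis genes. The rules for reading the last 2 were made more cautious after their values were known, so that both now leave the question open.

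Keratins and most interleukin 1 family genes were higher in the resistant line and metallothioneins lower, in calls that were lost when camera estimated the correlation. Among 15 families searched in resistant against shYAP_TAZ, camera called keratins (15 of 19 higher and 3 lower, adjusted p = 1.2e-04), the interleukin 1 family (6 of 8 higher and 2 lower, adjusted p = 0.00402) and metallothioneins (4 of 4 lower, adjusted p = 0.0222). None held with an estimated correlation (adjusted p = 0.169, 0.169 and 0.349). Some higher members passed the low-count filter only through the resistant group. KRT17, KRT6B, KRT3 and IL36G, chosen after their values were seen, had 13, 7, 2 and 3 counts over the shYAP_TAZ libraries. The keratin and interleukin 1 calls, here and against shNTC, therefore rest in part on that selection. IL37 went from 0.354 to 7.67 CPM, the receptor antagonist IL1RN from 3.67 to 20.5 CPM and MT2A from 104 to 47.7 CPM, while IL33 and IL36RN were lower, all genes chosen after their values were seen. Reads of keratins and metallothioneins can be shared with near-identical copies. Against shNTC, keratins (17 of 19 higher, adjusted p = 4.0e-07), S100A genes (10 of 12 higher, 1.2e-04), HLA class I genes (4 of 5 higher, 0.0227), histones (14 of 25 higher and 5 lower, 0.0317), the interleukin 1 family (6 of 8 higher and 1 lower, 0.0227) and ZNF zinc fingers (183 of 375 lower and 49 higher, 0.00265) were called. With an estimated correlation their adjusted p ran from 0.0802 to 0.44. No family was called after knockdown.

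Parts of the cell cycle list leaned the same way after knockdown and different ways in resistant against shYAP_TAZ. All 12 mitotic members fell after knockdown (median -2.06) and rose in the resistant line (median 1.67 against shYAP_TAZ). Against shNTC 2 of them were higher and 6 lower (median -0.19). The 6 MCM helicase genes fell after knockdown in 5 cases (median -0.52) and did not rise as a group in the resistant line, where 1 was higher and 3 were lower (median -0.36 against shYAP_TAZ). Their difference from the mitotic part was not tested.

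Genes of chromosome 9 were lower in the resistant line, with a median of -0.55 against shYAP_TAZ over 462 genes (MAD 0.588, genome -0.01), and 0 of 10000 random gene sets lay as far from the genome, as was also the case for chromosomes 2, 5, 6, 8, 12 and 15. Correction for GC content, transcript length and level left -0.517, which argues against such a bias as the whole cause. Of the genes 81.0% were lower. A few strong changes cannot move a median, so this share adds no separate evidence against them. The per-library medians were -0.551, -0.538 and -0.532 in the resistant libraries against -0.00881 to 0.0128 in shYAP_TAZ. In 10 of 11 windows of 10 Mb the median lay below that of the genome, which is consistent with a lower copy number of chromosome 9 in the resistant line, although DNA was not measured and chromosome 6 was lower in 14 of 14 windows (median -0.30). Regulation across the chromosome and a clone selected in the tumour stay open and were not tested.

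The sensitive lines differed by a shift of this kind as well. Genes of chromosome 8 were lower in shYAP_TAZ than in shNTC (median -0.31 over 399 genes, 71.7% lower, 11 of 12 windows below the genome median). After the same correction -0.295 remained, and 0 of 10000 random gene sets lay as far before it. The latter was also the case for chromosome 19, which lay 0.137 above the genome median, and 0.022 after correction. Fold changes of chromosome 8 genes in that comparison therefore hold a difference along the chromosome beside any effect of the hairpins, and its origin was not tested.

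In the resistant line 4 of 6 tested fibroblast markers were higher and 2 lower than in shYAP_TAZ, without a list call (adjusted p = 0.464), and the 3 tested of 12 leukocyte markers were higher (adjusted p = 0.0264, and 0.658 with an estimated correlation). The line had passed through a mouse, so host cells could have brought reads. The abundant markers COL1A2, COL3A1, DCN, LUM, PTPRC and TYROBP summed to 0.196 CPM in the resistant libraries and 0.284 CPM in shYAP_TAZ. None of these genes had passed the low-count filter, so a low sum was known in advance. Reads were aligned to the human genome, and whether mouse reads of these genes would be counted there was not tested. The sum therefore cannot decide whether mouse fibroblasts or leukocytes were the source of the higher markers. Of 25 fixed markers of these types 8 reached 1 CPM. Mouse reads in other genes were not tested. Mouse host cells and expression of the higher markers by the tumour cells both stay open.

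The YAP/TAZ-TEAD target list did not fall after knockdown. A failed knockdown or swapped libraries are argued against by YAP1 and WWTR1. With 2 standard errors added, the higher of their log2 fold changes was -1.179. The 14 targets with a mean of at least 10 CPM had a median of -0.00274, with 4 higher and 5 lower. These better measured members thus showed no fall as a set. Their spread between genes (MAD 0.746), which holds rises beside falls, puts the lower bound of the median at -0.502. This bound takes the 14 genes as a sample of such targets. For such targets at large, a median fall of about -0.5 therefore cannot be told apart from none. The remaining YAP1 and WWTR1 transcripts, other inputs to these genes and time after induction may also contribute and were not tested.

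The 6 libraries of resistant and shYAP_TAZ allow 10 divisions into groups of 3, too few for a share under 0.05. The real division, 1 of 10 for each count, gave 10142 called genes, 2375 at 2-fold, 11 lists and 4985 genes moving back, and the highest of the other 9 gave 0, 0, 8 and 0. In those 9 edgeR found 86 to 286 genes at an unadjusted p under 0.05 and limma-voom called 0. Each of those 9 mixes libraries of both groups, so the difference between the groups adds to the spread within each set. Their 0 gene calls were thus fixed in advance and cannot measure chance. Each also keeps part of the group difference, so their list calls are not calls without a difference.

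X-linked cancer-testis genes appeared in the resistant line, where SSX1 and MAGEB2 went from no count to at least 1 CPM and MAGEA1 reached 0.811 CPM. These 3 passed the low-count filter only through the resistant group and the family was chosen because of them, so its group test (adjusted p = 0.16) cannot speak for or against a rise of the family, which stays open. The other measured member, MAGEB17, was lower.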
